A study of Mus musculus with 35 samples.

How the data were processed

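The deposited table holds raw read counts per gene for 18 libraries, 1 for each of 18 mouse lymphoma cell lines, made with a 3' RNA library kit and read as single ends of 75 bp. Per the labels, 15 M reads were aimed at for each sample, while the counts in the table sum to between 3020184 and 4621443 per library (median 3838170.5). Per the submitters' processing notes, cutadapt 1.16, HISAT2 2.1.0, SAMtools 1.4.1, featureCounts 1.6.0, edgeR 3.16 and limma 3.4.6 were used with the mouse builds mm10 and GRCm38. The order of these tools, the gene annotation and the strand setting are not given in the sources used here. The values were checked to be whole numbers that differ between all columns, and no normalization had been applied to them.

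The labels list 35 samples, 17 in full serum (10% FCS) and 18 after serum deprivation (1% FCS for 24 h). The columns of the table are named by guide and cell line and do not state the serum condition. They were assigned to the serum-deprived samples because the 18 names are exactly the lines listed under deprivation, among them line 2, which has no full-serum sample in the labels. For the other 17 lines a name fits a sample in either condition, so the serum condition of a library rests on this match, while its guide and line are given in the column name. Of 13 comparisons planned, 4 were made; the 9 that need full-serum values (genotypes in full serum and the response to serum) were not analysed here.

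The libraries fall into 3 genotypes of 6 lines each: control guide, Depdc5 knockout and Nprl3 knockout. The comparisons were each knockout against control, the knockouts against each other, and the mean of both knockouts against control (GATOR1 KO). Replicates are separate cell lines in the labels, which do not say whether the lines come from separate mice. The replicate numbers of the labels stand for different cell lines in each genotype, and the labels name nothing that lines with the same number share, so no pairing was used; a fit with the number as a block is among the alternatives.

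Computation used R 4.3.3. Genes were kept by edgeR 4.0.16's filterByExpr (minimum count 10, minimum total count 15), which left 9506 of 27179 genes and 99.7% of the counts; 10650 genes had no count in any library. Libraries were scaled by TMM and tested with edgeR's quasi-likelihood test in a model with 1 mean per genotype over all 18 libraries, two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold for a call. No symbol is given for 1312 genes (0.165% of counts), and 35 of them were given a symbol through a RefSeq table of Entrez identifiers. Coordinates are GRCm38. Levels are CPM, the counts scaled to the library total, as mean ± SD over the 6 lines of a genotype; log2 changes and their standard errors come from the fit. A level of 0 allows up to 3 counts per library, or 0.649 to 0.993 CPM over the libraries. Where all control lines had 0 counts, folds were computed against 3 counts over the group, and with 1 to 3 counts the ratio has a 95% exact binomial interval; floors and intervals cover counting error only.

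Choices made before the data were examined were the tests, 35 gene lists, most alternatives and the rule for named genes. The rule takes, in each comparison with calls, the 10 higher and the 10 lower called genes with the smallest p among those with an average log2 CPM of at least 1, without immunoglobulin and T cell receptor segments and provisional names. It adds up to 4 called members with the smallest p for each list described, and always Depdc5, Nprl3, Nprl2, Myc, Trp53, Cdkn2a, Cdkn1a and Mdm2. Without calls, the 3 genes with the smallest p are given. Of the 35 lists, 29 had at least 4 measured members and were tested with fry in limma 3.58.1, which asks whether the genes of a list move, on balance, to 1 side. Camera with a preset correlation of 0.01 and with an estimated correlation were alternatives.

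Other alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, limma-voom, no filter on low counts, fits of only the groups compared, both knockouts as 1 group, and leaving out each line. Added after seeing the data were fits without the genes of chromosomes 11 and 19, without those of chromosomes 11, 15, 16, 18 and 19, and without lines 282 and 263. Chromosome medians were taken per line over genes with a mean log2 CPM of at least 4, relative to the median of all lines. The test was also tested on simulated data with 100 genes changed by 2-fold and 100 by 4-fold: 79%, 71% and 80% of the 2-fold changes and 94%, 95% and 91% of the 4-fold changes were recovered for Depdc5 KO, Nprl3 KO and GATOR1 KO, and 2.81%, 5.14% and 3.93% of calls were false. Immunoglobulin gene segments were not described as single genes, because they differ between clonal lymphomas.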

Results

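Gene expression was measured in 18 cell lines of mouse lymphoma driven by a Myc transgene active in B cells. The lines express Cas9 with a control guide (named hBim in the labels), a guide against Depdc5 or a guide against Nprl3, with 6 lines per genotype. Depdc5, Nprl3 and Nprl2 are the subunits of GATOR1, a complex that restrains the growth kinase complex mTORC1 when amino acids are scarce. The series title names GATOR1 as a tumour suppressor in lymphoma driven by MYC, and the comparisons ask how lines without a GATOR1 subunit differ in expression from control lines. Library totals lay between 3020184 and 4621443 counts. The table does not state whether a library came from full or deprived serum; its 18 columns match the lines listed under serum deprivation, and groups are named here by genotype alone. Because p-values measure the spread between these lines, they hold for the population of lines only as far as the lines arose separately, which the labels do not state. Some pairs of lines were closer than others (r up to 0.979 among control lines, median 0.927), and a shared origin was not tested. Library indexes ran from 8 to 13 in the controls, 14 to 19 in the Nprl3 knockouts and 20 to 25 in the Depdc5 knockouts, so library order and genotype cannot be told apart.

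The targeted genes were still counted in their knockout lines. Depdc5 (chromosome 5, 32863646 to 32994233) stood at 12.9 ± 1.81 CPM in control, 16.8 ± 5.02 in Depdc5 KO and 15.4 ± 3.07 in Nprl3 KO lines (SD, n = 6 each). Nprl3 (chromosome 11, 32231963 to 32267707) stood at 4.41 ± 1.12, 5.50 ± 1.29 and 3.45 ± 2.26 CPM. Nprl2 (chromosome 9, 107542177 to 107545706) stood at 14.2 ± 2.95, 17.6 ± 3.69 and 17.98 ± 0.664 CPM. The log2 change was 0.33 for Depdc5 in Depdc5 KO (adjusted p = 0.206) and -0.37 for Nprl3 in Nprl3 KO (adjusted p = 0.522), neither called. Counts from the 3' end of a transcript check nothing about an edit elsewhere in the gene, and the cut sites are not given in the sources used here.

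Depdc5 knockout lines differed from control lines in 1814 of 9506 genes, 899 higher and 915 lower, and by more than 2-fold in 296 and 204. Myc itself (chromosome 15, 61985341 to 61990361), the driver of these lymphomas, fell from 686 ± 337 CPM in control to 302 ± 59.0 in Depdc5 KO lines (log2 change -1.21 ± 0.22 SE, adjusted p = 0.00108). Control line 384, at 1337.9 CPM, raised the control mean, with the nearest control line at 655. The counts do not separate the transgene from the endogenous gene. Genes close to silent in control lines were expressed in the knockout lines. S100a6 (chromosome 3, 90612894 to 90614414), a calcium-binding protein, rose from 1.46 ± 1.78 to 1130.5 ± 415 CPM (log2 change 9.54 ± 0.83, adjusted p = 9.05e-07) and was higher in 6 of 6 lines than in any control line. Lifr (chromosome 15, 7090610 to 7197489), the receptor of leukaemia inhibitory factor, had 0 counts in control lines and 14.3 ± 2.46 CPM in Depdc5 KO lines, at least 108-fold higher (adjusted p = 9.05e-07).

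Ccnd2 (chromosome 6, 127125162 to 127152188), the G1 cyclin D2, stood at 0.135 ± 0.229 CPM in control and 26.0 ± 17.2 in Depdc5 KO lines, a ratio of 200.4 (95% interval 68.3 to 975). Dlk1 (chromosome 12, 109452485 to 109463336), an imprinted membrane protein, had 1 count over the control lines and 114 ± 70.7 CPM in Depdc5 KO lines, a ratio of 2682.7 (481 to 106000). Isl1, a homeobox transcription factor, was at least 54.2-fold higher, and Elfn1 at least 59.4-fold. S100a4 (log2 change 6.98) and the mitochondrial sulfur dioxygenase Ethe1 (0.87) also rose. Among the lower genes, Pim3 (chromosome 15, 88862194 to 88865726), a serine/threonine kinase, fell from 220.4 ± 27.4 to 105 ± 18.2 CPM (log2 change -1.11, adjusted p = 1.38e-05). Gsto1 (chromosome 19, 47854973 to 47864790), a glutathione transferase, fell from 298 ± 67.0 to 139.5 ± 8.03 CPM (-1.12, adjusted p = 3.65e-06). The phospholipase Pla2g12a (-1.12), the endolysosomal channel Mcoln2 (-1.15) and Ccdc40 (-6.26) fell too. Znrd2 (-1.28), Twnk (-1.08), Rab11fip2 (-1.204), Abhd17b (-0.98) and Pdcd11 (-0.72) fell and, like Gsto1, lie on chromosome 19, which was lower as a whole in these lines.

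Nprl3 knockout lines differed from control lines in 1437 genes, 769 higher and 668 lower, and by more than 2-fold in 279 and 126. Myc fell to 332 ± 40.1 CPM (log2 change -1.06 ± 0.22, adjusted p = 0.00343). S100a6 rose to 864 ± 454 CPM (9.18 ± 0.82, adjusted p = 1.36e-06), with 26.4 CPM in line 263 and 792 to 1253.4 in the other 5 lines; limma-voom did not call it (adjusted p = 0.0619). Lifr reached 14.03 ± 5.30 CPM, at least 107-fold above control (adjusted p = 9.17e-07), Isl1 at least 58.2-fold and Elfn1 at least 73.9-fold. Ccnd2 stood at 43.9 ± 22.4 CPM, a ratio of 337 (115 to 1637.6). Dlk1 stood at 151 ± 132 CPM, a ratio of 3501.3 (628 to 138330). S100a4 (log2 change 7.10) and Id2 (3.00), an inhibitor of helix-loop-helix transcription factors, rose. Pim3 fell to 91.4 ± 10.4 CPM (-1.29, adjusted p = 1.83e-06), Gsto1 to 134 ± 11.6 (-1.17, adjusted p = 1.83e-06) and Fth1, the ferritin heavy chain on chromosome 19, from 1631 ± 220.1 to 892 ± 174 (-0.88, adjusted p = 1.94e-05). Pla2g12a (-1.08), Dqx1 (-2.38), Mpp1 (-1.38) and the kynurenine monooxygenase Kmo (-2.65) fell, as did Twnk (-1.22) and Znrd2 (-1.27) on chromosome 19.

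**Figure D1:**
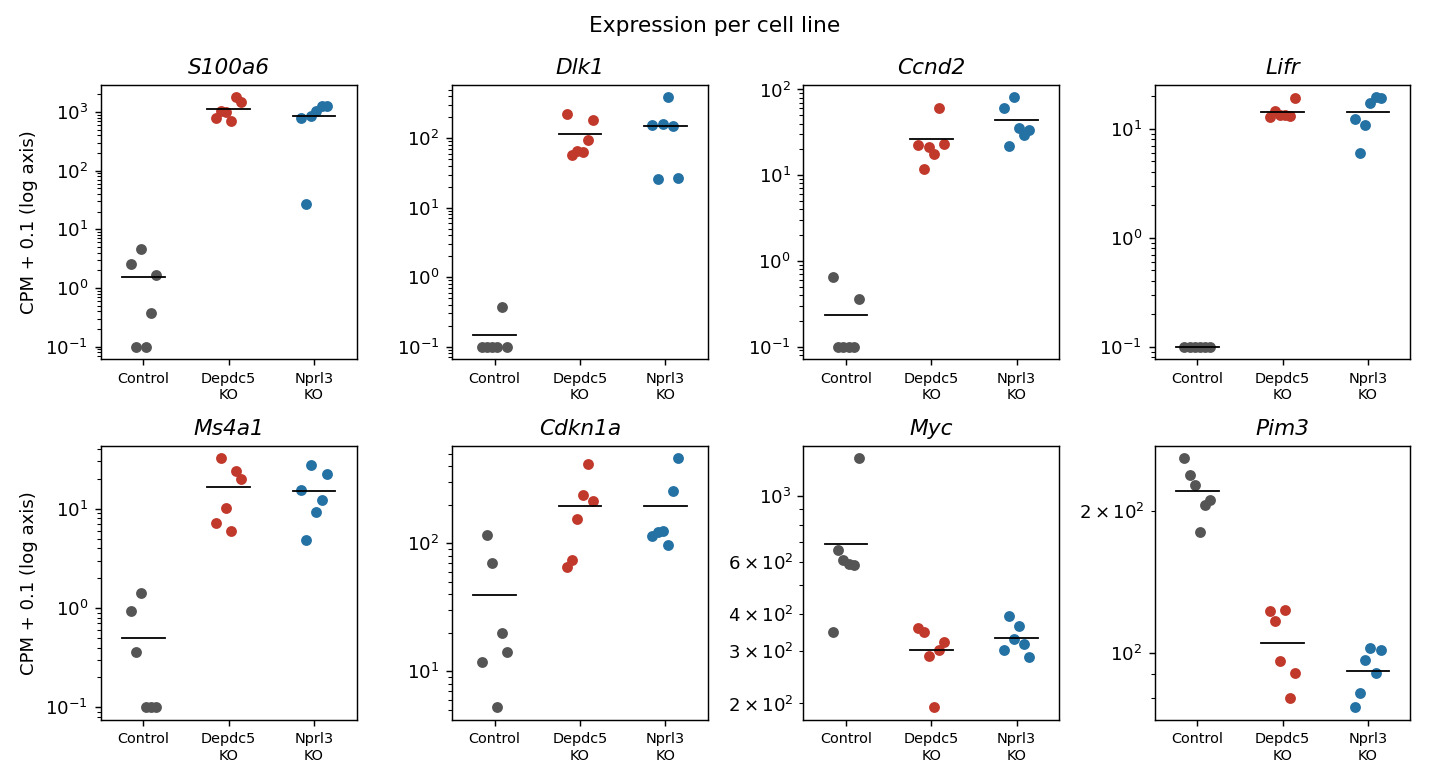
Counts scaled to the library total (CPM plus 0.1, log axis) of named genes in each cell line, by genotype; points are lines and horizontal bars are means of 6 lines. Lifr has 0 counts in the 6 control lines, and S100a6 in Nprl3 knockout line 263 stands at 26.4 CPM.

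Of the p53 pathway genes fixed for report, Cdkn1a (chromosome 17, 29090979 to 29100722), the cell cycle inhibitor p21 and a p53 target, rose from 39.4 ± 44.1 CPM in control to 194 ± 131 in Depdc5 KO (log2 change 2.26 ± 0.63, adjusted p = 0.0174) and 196 ± 142 in Nprl3 KO lines (2.31 ± 0.63, adjusted p = 0.0185). The calls were lost without 1 line, with a log2 change of 1.88 (adjusted p = 0.0521) without Depdc5 KO line 394 and of 1.83 (0.0587) without Nprl3 KO line 270. Trp53, which encodes p53, stood at 84.2 ± 13.02 CPM in control, 105 ± 7.84 in Depdc5 KO and 92.2 ± 45.1 in Nprl3 KO lines (log2 changes 0.29 and 0.12, adjusted p = 0.438 and 0.791). Mdm2, the ubiquitin ligase of p53, stood at 90.5 ± 14.2, 113 ± 33.5 and 114 ± 24.5 CPM (0.28 and 0.32, adjusted p = 0.269 and 0.218). Cdkn2a, which encodes p19Arf and p16Ink4a, had too few counts to be tested, with 4.91 ± 9.20, 0.221 ± 0.542 and 0.615 ± 1.21 CPM and most of the control counts in line 2.

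Among the lists fixed for growth control and metabolism, values below are for Depdc5 KO and then Nprl3 KO. Lysosome genes (34 measured) were higher as a group (fry adjusted p = 0.00645 and 0.00623), with 8 higher and 2 lower, and 7 higher and 1 lower, and 11 and 2, and 12 and 1, when adjusted over the list alone; adjusted p = 0.480 and 0.433 with an estimated correlation. Its called members include the acid lipase Lipa on chromosome 19 (log2 change 1.33 and 1.14), the mannosidase Man2b1 (0.64 and 0.62) and cathepsin Z, Ctsz (0.68 and 0.69). Fatty acid synthesis genes (15) were higher (0.0449 and 0.0329), with 6 higher and 2 lower, and 4 and 1, and 8 and 2, and 6 and 2, adjusted over the list alone; adjusted p = 0.636 and 0.637 with an estimated correlation. The desaturase Scd1 (0.92 and 0.98), Acss2 (1.17 and 1.53) and Srebf1, the regulator of this pathway (0.74 and 0.70), rose, and the acyltransferase Gpam (-1.55 and -1.41) fell. This list lost its call without the genes of chromosomes 11 and 19 (adjusted p = 0.907 and 0.334), where Scd1, Gpam and Srebf1 lie, and camera with the preset correlation did not call it (0.223 and 0.174).

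Cholesterol efflux genes (5) were higher (fry adjusted p = 2.72e-04 and 6.38e-04), with 3 higher, and 3 higher and 1 lower, and 4, and 4 and 1, adjusted over the list alone; adjusted p = 0.207 and 0.320 with an estimated correlation. The sterol exporter Abcg1 (1.72 and 2.00) and Lpcat3 (0.53 and 0.51) rose in both, and Apoe (-0.42) fell in Nprl3 KO. Pentose phosphate genes (7) were higher (2.64e-04 and 9.33e-04), with 4 higher in each, and 5 and 4 adjusted over the list alone, among them transaldolase, Taldo1 (0.46 and 0.41), and Pgd (0.34 and 0.35); adjusted p = 0.207 and 0.320 with an estimated correlation. Oxidative stress genes (9) had 4 higher and 1 lower in each, as also when adjusted over the list alone, with Prdx1 (0.60 and 0.42), Txnrd1 (0.59 and 0.44) and Hmox1 (2.22 and 1.96) higher and Fth1 lower. The list was called in Depdc5 KO (0.00817; 0.143 by camera with the preset correlation) and not in Nprl3 KO (0.0774); adjusted p = 0.484 and 0.637 with an estimated correlation. ATF4 targets of the amino acid response (26) had 3 and 4 higher and none lower, and 1 higher, and 6 higher and 1 lower, adjusted over the list alone, among them Psph of serine synthesis (1.20 and 1.21). The list was called in Depdc5 KO (0.0331) and not in Nprl3 KO (0.0859); adjusted p = 0.484 and 0.637 with an estimated correlation.

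Of the lists fixed for ribosomes, respiration and nucleotides, each of the following was called lower in 1 knockout. Cytosolic ribosomal protein genes (79) had 18 lower and 1 higher in Depdc5 KO, and 11 and 1 in Nprl3 KO, and 21 and 1, and 11 and 1, adjusted over the list alone, with median log2 changes of -0.19 and -0.13. The list was called in Depdc5 KO (fry adjusted p = 0.0331) and not in Nprl3 KO (0.135); adjusted p = 0.484 and 0.637 with an estimated correlation. Rplp0 (-0.28 and -0.24) fell in both, and Fau on chromosome 19 (-0.65) and Rpl36a (-0.43) fell in Depdc5 KO; these genes have close copies elsewhere in the genome. Nuclear genes of oxidative phosphorylation (48) had 12 lower and 0 higher, and 7 and 0, and 13 and 6 lower adjusted over the list alone, including Ndufb8 (-0.46) and Cox8a (-0.71), both on chromosome 19. The list was called in Depdc5 KO (0.0449) and not in Nprl3 KO (0.207); adjusted p = 0.484 and 0.644 with an estimated correlation, and without chromosomes 11 and 19 the Depdc5 KO call was lost (0.102). Ribosome biogenesis genes (37) had 4 lower and 2 higher, and 3 lower and 0 higher, and 3 lower in each adjusted over the list alone, with Nolc1 (-0.81 and -0.73, chromosome 19) and the polymerase subunit Polr1c (-0.30 and -0.31). This list was called in Nprl3 KO (0.0250) and not in Depdc5 KO (0.175); adjusted p = 0.433 and 0.718 with an estimated correlation. Nucleotide synthesis genes (19) had 4 lower and 1 higher, and 5 lower and 0 higher, as also adjusted over the list alone, with Adsl of purine synthesis (-0.43 and -0.56). This list was called in Nprl3 KO (0.00487) and not in Depdc5 KO (0.0559); adjusted p = 0.320 and 0.484 with an estimated correlation.

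The BCL2 family, p53 target and interferon lists were called higher in both knockouts and mature B cell genes in Depdc5 KO. Genes of the BCL2 family (11) were higher in both knockouts (fry adjusted p = 5.94e-04 and 6.38e-04), with 2 higher and 0 lower in each, and 2 and 4 adjusted over the list alone; adjusted p = 0.207 and 0.320 with an estimated correlation. The list holds proteins that promote and proteins that prevent cell death. Bcl2l11, which encodes the pro-death protein Bim, rose by 0.50 and 0.50. The guide of the control lines is named hBim in the labels, and whether it acts on Bcl2l11 was not tested. The survival gene Bcl2l1 was not called (0.81 and 0.95, adjusted p = 0.123 and 0.0792). Targets of p53 (28) were higher (0.0405 and 0.0416), with 8 higher and 2 lower, and 9 and 1, and 11 and 2 in each adjusted over the list alone; adjusted p = 0.484 and 0.637 with an estimated correlation. Ccng1 (1.33 and 1.43) and Btg2 (0.89 and 1.10), which restrains proliferation, rose, as did Trp53cor1 (2.83 and 2.59), a neighbour of Cdkn1a. The call of the p53 list was lost in 8 of 12 fits that left out 1 line in each knockout (adjusted p up to 0.0952 and 0.113), without lines 282 and 263 (0.0759 and 0.0747) and, in Nprl3 KO, in the fit of only the groups compared (0.0635) and without chromosomes 11, 15, 16, 18 and 19 (0.0581). Interferon response genes (10) were higher (0.00293 and 0.00487), with 4 and 3 higher and 0 lower, and 5 and 4 adjusted over the list alone, among them Trim30a (2.45 and 2.19) and the RNA sensor Ddx58 (1.79 and 1.70); adjusted p = 0.384 and 0.320 with an estimated correlation. Mature B cell genes (14) had 4 higher and 1 lower, and 2 and 1, and 4 and 1, and 4 and 2, adjusted over the list alone. Ms4a1, which encodes CD20, rose from 0.401 ± 0.553 CPM in control to 16.5 ± 10.5 and 15.2 ± 8.44 CPM (5.24 and 5.14), and Cd40 rose by 2.28 and 2.06. This list was called in Depdc5 KO (0.00795) and not in Nprl3 KO (0.0802); adjusted p = 0.480 and 0.637 with an estimated correlation.

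**Figure D2:**
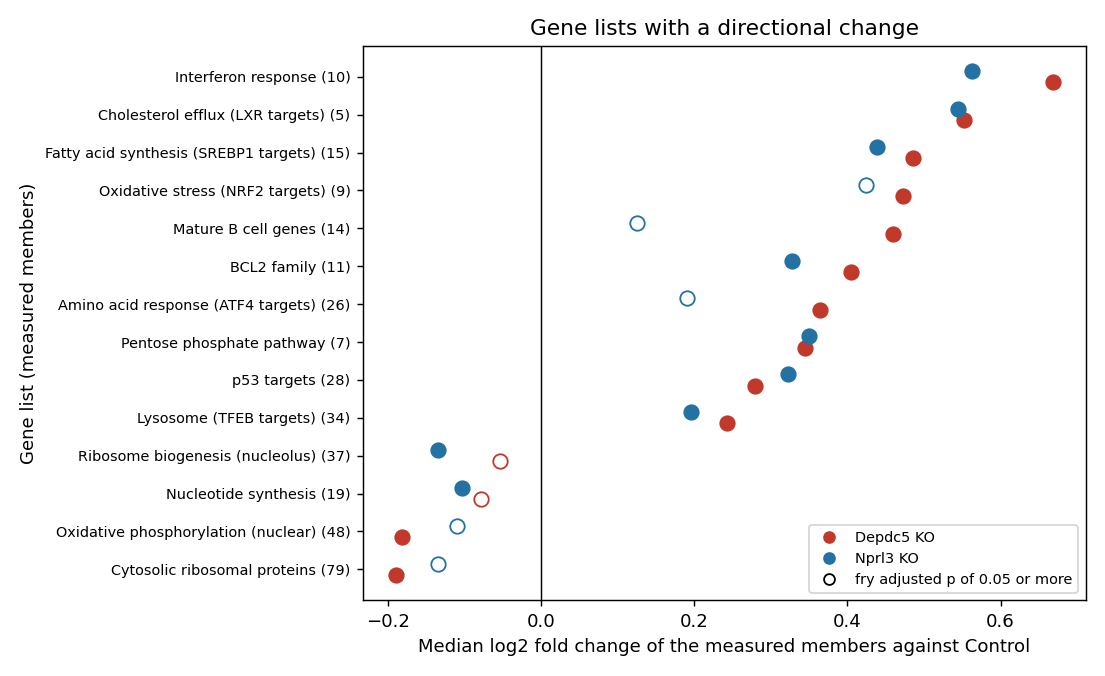
Median log2 change against control of the measured members of the 14 gene lists that fry called in at least 1 knockout, for Depdc5 KO (red) and Nprl3 KO lines (blue); open circles have a fry adjusted p of 0.05 or more. The BCL2 family medians are 0.40 and 0.33, and the ribosomal protein medians are -0.19 and -0.13.

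The other 15 lists tested were called in neither knockout, and in these, too, single members passed the test. Genes of the GATOR and mTORC1 machinery (34; fry adjusted p = 0.120 and 0.201) had 3 higher and 3 lower, and 2 and 2, with the arginine sensor relative Castor2 (3.06 and 3.45) and the sestrin Sesn3 (0.98 and 0.96) higher. Hypoxia genes (14; 0.687 and 0.207) had 3 higher and 3 lower, and 4 and 1, with Ndrg1 (3.37 and 3.08) and the mTORC1 inhibitor Ddit4 (1.10 and 1.44) higher. Glycolysis genes (20; 0.271 and 0.299) had 5 higher and 1 lower, and 3 and 0, with Aldoc (2.32 and 2.21) and Pfkfb3 (0.48 and 0.56) higher. Cholesterol synthesis genes (23; 0.192 and 0.0802) had 5 higher and 1 lower, and 4 and 1, with Ebp (0.52 and 0.74) higher and Sqle (-0.37 and -0.35) lower. Other MYC targets (21; 0.897 and 0.249) had 1 higher and 1 lower, and 1 and 5, with the transferrin receptor Tfrc (-0.52 and -0.42) lower in both and Cdk4 (-0.59) lower in Nprl3 KO. Tfrc lost its Nprl3 KO call when only the groups compared were fitted (adjusted p = 0.0526). Mitosis genes (30; 0.966 and 0.602) had 2 higher and 4 lower, and 1 and 2, with Bub1 (0.45 and 0.48) higher and Cdc25b (-0.86 and -0.91) lower. Heat shock genes (11; 0.120 and 0.572) had 1 higher in each, Hspa1b (2.86 and 3.83), which has a near-identical neighbour. Autophagy (24; 0.896 and 0.401), tRNA synthetases (20; 0.181 and 0.240), the unfolded protein response (19; 0.966 and 0.918), DNA replication (26; 0.175 and 0.548), pro-B and pre-B cell genes (9; 0.192 and 0.457), NF-kB targets (9; 0.221 and 0.813), FOXO targets (15; 0.403 and 0.641) and immediate early genes (13; 0.192 and 0.207) were not called. For FOXO targets the median log2 changes (-0.19 and -0.09) and the direction of fry (higher) differ in sign. Plasma cell genes (3 measured), T and NK cell markers (1), myeloid markers (1), stromal and endothelial markers (1) and erythroid markers (0) were too few to test, and the mitochondrial genome has 0 of its 13 genes in the table.

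The calls in both knockouts overlapped. Of the called genes 1115 were shared, 595 higher and 520 lower in both and 0 in opposite directions, where independent calls would share 72.7 and 64.3; a further 699 were called in Depdc5 KO alone and 322 in Nprl3 KO alone. Both comparisons use the same 6 control lines, which alone ties them. When the controls were divided into 3 and 3, so that the comparisons shared no library, a median of 228.5 genes (182 to 267 over 10 divisions) were higher and 205.5 (156 to 215) lower in both, and up to 27 moved in opposite directions. With fewer control lines per comparison, total calls also fell, to medians of 1211.5 in Depdc5 KO and 834.5 in Nprl3 KO. The lower overlap is therefore not a measure of the shared controls alone. The correlation of log2 changes across genes was 0.905 with shared controls, 0.712 (0.464 to 0.776) with divided controls, and 0.508 in simulated unchanged data with shared controls; genes are not independent replicates.

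The mean of both knockouts differed from control in 2296 genes, 1144 higher and 1152 lower, and by more than 2-fold in 326 and 200. Myc changed by -1.14 (adjusted p = 2.49e-04) and Cdkn1a by 2.28 (adjusted p = 0.00828), while Nprl2 was not called (0.30, adjusted p = 0.0931). Cstf2t on chromosome 19, a cleavage stimulation factor copy, fell by 2.55. By fry 13 lists were called, 10 higher and 3 lower: lysosome (0.00262), fatty acid synthesis (0.0242), ATF4 targets (0.0273), p53 targets (0.0238), BCL2 family (1.17e-04), mature B cell (0.0231), interferon (0.00171), cholesterol efflux (1.17e-04), oxidative stress (0.0168) and pentose phosphate (1.17e-04) higher, and ribosome biogenesis (0.0273), ribosomal proteins (0.0273) and nucleotide synthesis (0.00638) lower. With an estimated correlation 0 lists were called, with adjusted p = 0.284 to 0.545 for these lists.

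Nprl3 KO and Depdc5 KO lines differed in 0 of 9506 genes by edgeR's quasi-likelihood test, with 441 genes at an unadjusted p under 0.05; DESeq2 called 2 genes and limma-voom 0. The smallest p belonged to D130062J21Rik (log2 change 1.12 ± 0.18, adjusted p = 0.0663), Gm4342 (1.17 ± 0.23, adjusted p = 0.255) and the kinase Prkd2 (-0.75 ± 0.15, adjusted p = 0.255). DESeq2 called D130062J21Rik (adjusted p = 9.74e-05) and Prkd2 (0.00841). Nprl3 was -0.65 (adjusted p = 0.975), Myc 0.15 (0.988) and Cdkn1a 0.05 (0.996). By fry 0 lists were called (smallest adjusted p = 0.907), and camera with the preset correlation called ribosome biogenesis (0.0283) and mature B cell genes (0.0283) lower and ribosomal proteins (0.0283) and oxidative phosphorylation (0.0395) higher in Nprl3 KO; camera with an estimated correlation called 0. A p above the threshold does not show that both knockouts act alike.

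Chromosome 19 was lower as a whole in the knockout lines. Its median expression relative to all lines was 0.37 ± 0.03 (log2, SD, n = 6) in control, -0.11 ± 0.03 in Depdc5 KO and -0.02 ± 0.20 in Nprl3 KO lines, where line 263 stood at 0.37 and the others between -0.17 and -0.02. Of 358 tested genes on it 203 were lower and 12 higher in Depdc5 KO and 137 lower and 13 higher in Nprl3 KO, which makes 22.2% and 20.5% of all lower calls from 3.77% of the genes tested. The median log2 change was -0.49 and -0.36. Chromosome 11 stood at -0.11 ± 0.04 in control, 0.13 ± 0.22 in Depdc5 KO and 0.07 ± 0.22 in Nprl3 KO lines, with 0.26 to 0.39 in lines 268, 270, 392, 394 and 396, and 169 of its 817 tested genes were higher in Depdc5 KO and 113 in Nprl3 KO. Without the genes of both chromosomes 1359 genes were called in Depdc5 KO, 1110 in Nprl3 KO, 0 between the knockouts and 1793 in the mean of both, of 8331 tested. Chromosomes 15, 16 and 18 were lower by less. On chromosome 16 the median log2 change was -0.24 in Depdc5 KO and -0.20 in Nprl3 KO, with 80 and 59 of 308 tested genes lower (8.74% and 8.83% of all lower calls from 3.24% of the genes tested). On chromosome 15, where Myc, Lifr and Pim3 lie, it was -0.20 and -0.17, with 63 and 55 of 376 lower, and on chromosome 18 it was -0.17 and -0.06, with 34 and 13 of 236 lower. Control lines 2 and 383 stood highest among the control lines on these, at 0.49 and 0.30 on chromosome 15. Without the genes of chromosomes 11, 15, 16, 18 and 19, 1158 genes were called in Depdc5 KO and 964 in Nprl3 KO of 7411 tested, and in Nprl3 KO the nucleotide synthesis (adjusted p = 0.0979) and ribosome biogenesis (0.0581) lists lost their calls. These chromosome medians were looked at after the data were seen.

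**Figure D3:**
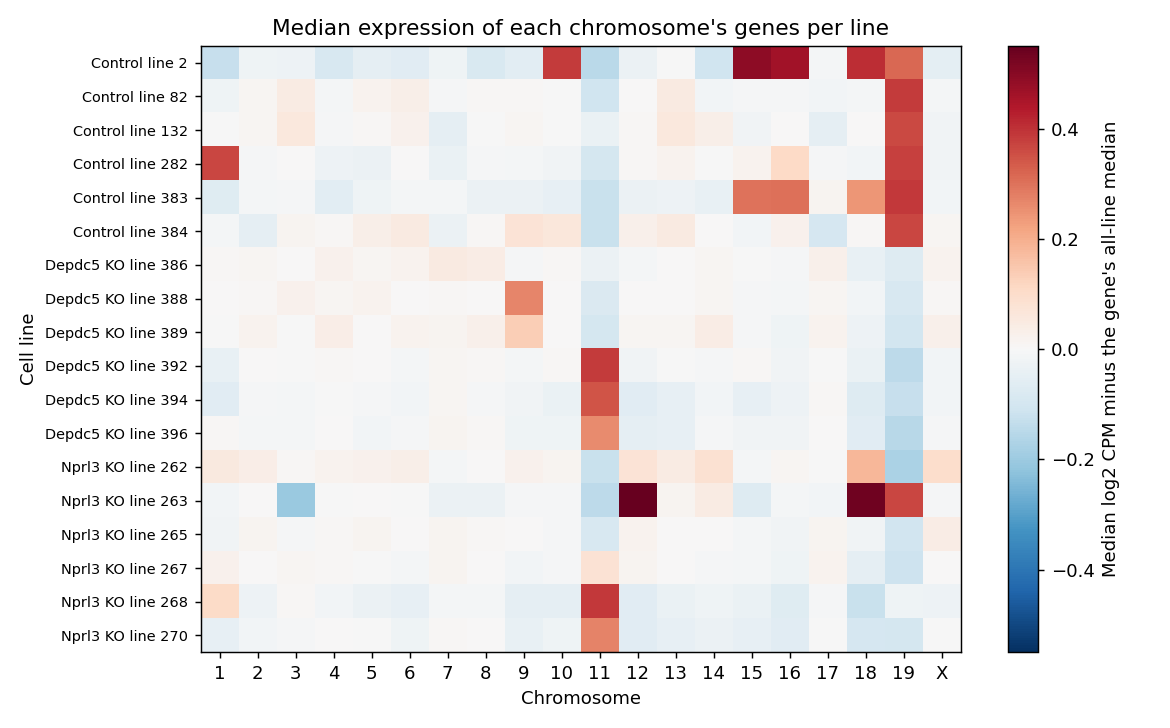
Median log2 expression of each chromosome's genes in each line relative to the median of all lines, as colours. Chromosome 19 lies between 0.31 and 0.39 in the 6 control lines and at 0.37 in Nprl3 KO line 263.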

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

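Tests of a GATOR1 effect in every line, of other cell types, of library order, of the founder of line 263, of the p53 list without chromosomes 11 and 19 and of its dependence on single lines (after 3 other forms) were chosen only after the results were seen. Of 56 groups of lines examined 9 held a line far from the others, by the gap to the nearest line over the range of the group. The cut-off was set for about 1 in 20 groups by chance. A single line above 0 among lines at 0 passes it by construction, as for Dlk1 in the controls. The 9 groups can therefore not be set against 1 in 20.

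Myc in Control line 384 stood at 1337.9 CPM, with the nearest control line at 655. Cdkn2a stood apart at 23.2 CPM in Control line 2 (nearest 5.17), 1.33 in Depdc5 KO line 389 (nearest 0) and 3.03 in Nprl3 KO line 265 (nearest 0.662). Lifr was 19.2 CPM in Depdc5 KO line 396 (nearest 14.5), and Ccnd2 was 59.97 CPM in Depdc5 KO line 394 (nearest 22.99). Dlk1 was 0.272 CPM in Control line 383, a single count, against 0 in the other control lines. The chromosome 19 median was 0.31 in Control line 2 (nearest 0.36) and 0.37 in Nprl3 KO line 263 (nearest -0.02).

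Chromosome 19 was higher in 6 of 6 control lines than in 11 of 12 knockout lines. Genes of other chromosomes matched on GC content and expression had a median log2 change of 0.023 in Depdc5 KO (range -0.04 to 0.08 over 1000 draws) against -0.48 for the chromosome 19 genes with a GC value, which argues against GC content or expression level as the source. Along the chromosome every 10 Mb bin with 10 or more genes was lower, the one nearest 0 at -0.35, which is consistent with a copy number difference of the whole chromosome, such as an extra copy in the control lines (log2 of 3 over 2 copies is 0.58). An effect of GATOR1 loss in every knockout line stays open, since 1 knockout line, 263, stood within the control range and a single library decides nothing. Why control and knockout lines would differ in copy number was not tested.

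Genes close to 0 in control lines and expressed in both knockouts form a set of 24 with at most 3 counts over the controls, of which 15 had more than 3 counts in every knockout line. T, NK, myeloid and erythroid cells in the knockout libraries are argued against as the source. Their markers with at most 3 control counts summed to at most 3.11% of the median gene of the set. Mean levels of Cd2 and Cybb were lower in the knockout lines, at 4.68 against 24.5 and at 0.759 against 18.5 CPM. Control levels were uneven. Cybb stood at 68.8 CPM in Control line 282 and 32.4 in 383, but at 4.43 in line 2 and 1.28 in 384. Cd2 stood at 1.28 CPM in Control line 384. These 2 means therefore add little on other cells. Stromal markers also reached 3.11%, with Col1a1, Col1a2, Col3a1 and Dcn at 0 knockout counts. That sum left out Sparc, also a stromal gene, which was counted with the endothelial markers. Sparc had 2 control and 66 knockout counts, most of the 74 behind the endothelial 28.8%, while Cdh5 had 6 and Kdr 2. Stromal and endothelial cells therefore stay open. Pecam1 stood at 46.8 CPM in control and 43.0 in knockout lines, and other cell types were not tested. Descent of line 263 from 1 founder clone with the 9 other knockout lines that had Xist above 100 CPM is excluded. Line 263 had 505 counts of Y-linked genes, against 0 in the other knockout lines. Descent from 1 founder clone otherwise stays open, as 0 knockout lines had 50 or more counts of heavy chain V segments. A steady trend along the library order (control, Nprl3 KO, Depdc5 KO, 6 places apart) is argued against for this set. Its median log2 change was -0.18 from Nprl3 KO to Depdc5 KO, against 5.43 from control to Nprl3 KO with control at 3 counts. A step between the control and the knockout libraries was not tested, as library order and genotype cannot be told apart. The set was also chosen as called higher in both knockouts, and no label names a batch. The effect of GATOR1 loss stays among the open explanations, untested apart from these.

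The p53 target list was called higher in both knockouts by fry, but not with an estimated correlation between genes (adjusted p = 0.484 and 0.637), which random lists ignore. Of 10000 random lists matched on expression, 0% had a median as high as the 0.28 in Depdc5 KO or the 0.32 in Nprl3 KO, which argues against the expression level of its genes as the source. Without chromosomes 11 and 19 the medians were 0.27 and 0.30 over 26 of 28 members. This argues against list members on these chromosomes as the source of the whole shift. The fry adjusted p of 0.0489 in Nprl3 KO and 0.0496 in Depdc5 KO lie at the threshold. Leaving out members cannot test an effect of these chromosomes on genes elsewhere. Relative to the mean of all lines, the list median was highest in lines 270 (0.56), 394 (0.47), 396 (0.26) and 268 (0.24). All are among the lines raised on chromosome 11. Line 392, also raised there, had 0.07, while line 263 had 0.18. This link was not tested. A single line as the only source is argued against, as 11 of 12 knockout lines had a median of the list above every control line. Some margins were small, with -0.09 in line 267 and -0.06 in line 265 against -0.12 in Control line 132, the highest control. The call was lost in 8 of 12 fits leaving out 1 line in each knockout. The median fell to 0.22 in Depdc5 KO without line 394 and to 0.17 in Nprl3 KO without line 270. Loss of GATOR1 as the source was not tested separately.

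For the number of genes, 100 splits of the lines into groups of the same sizes, the real one included, were counted. In Depdc5 KO 1 split gave as many as the real 1814 (highest other 76), in Nprl3 KO 1 gave as many as 1437 (highest other 592), and in the mean of both 1 gave as many as 2296 (highest other 4). This argues against an arbitrary grouping of the lines as the source of these numbers. With 100 splits the smallest possible share is 1 in 100. The splits treat the lines as separate and cannot test shared descent or a batch that follows genotype. The split with 592 genes, and the next with 375, differed from the genotypes by the exchange of Nprl3 KO line 263 with a control line (132 and 282). Between the knockouts the real count is 0, so all 100 splits gave at least as many by construction (highest other 7) and the splits test nothing.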

How the results depend on the processing

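Fits without chromosomes and without lines 282 and 263 were chosen after seeing the data. Under every alternative with a gene count, the numbers of genes in Depdc5 KO, Nprl3 KO and the mean of both stayed within 1.5 times the reported ones, except that only 954 genes were called in Nprl3 KO against Control when only the groups compared were fitted, with fewer samples to estimate spread, and that 1158 in Depdc5 KO and 1524 in the mean of both were called without chromosomes 11, 15, 16, 18 and 19, with fewer genes tested. The counts were 2049, 1724 and 2451 with DESeq2, 1800, 1503 and 2305 with limma-voom, 1819, 1433 and 2292 with DESeq2 size factors, 1857, 1447 and 2453 without a filter on low counts (16529 genes) and 1805, 1569 and 2303 without lines 282 and 263. With the replicate number as a block they were 1694, 1326 and 2126; deviations from the genotype means of lines with the same number correlated across genes by -0.08 to 0.35 over 18 pairs. None of the 12 pairs with a control line was above 0.1, while 4 of the 6 Depdc5 KO and Nprl3 KO pairs were, as were 8 of the 30 pairs of these knockouts with different numbers. Lines best correlated with their own number were 3 of 12 between the knockouts, 6 of 12 for control and Nprl3 KO (r up to 0.073) and 0 of 12 for control and Depdc5 KO; none were paired. With the block fry did not call ATF4 targets (0.0878), ribosomal proteins (0.0733) and oxidative phosphorylation (0.0529) in Depdc5 KO, ribosome biogenesis (0.0832) in Nprl3 KO, and ATF4 targets (0.0719), ribosome biogenesis (0.0742) and ribosomal proteins (0.0741) in the mean of both. Between the knockouts DESeq2 called 2 genes and the fit without these 5 chromosomes 1; the other tools and settings on all lines called 0. Leaving out 1 line gave 1410 to 1753 genes in Depdc5 KO, 1148 to 1627 in Nprl3 KO, 1939 to 2508 in the mean of both and 0 to 1 between the knockouts; the 1 gene, without line 262 or 396, was D130062J21Rik (adjusted p = 0.0378 and 0.0387).

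Camera with an estimated correlation called 0 lists in Depdc5 KO, 0 in Nprl3 KO and 0 in the mean of both. Between the knockouts, camera with the preset correlation called 4 lists. Why these results differ from those of fry was not tested. Camera with the preset correlation did not call oxidative stress (0.143 in Depdc5 KO, 0.153 in the mean of both), nucleotide synthesis in the mean of both (0.0837) or fatty acid synthesis (0.198 in the mean of both). Fits of only the groups compared lost ATF4 targets (0.0820) and ribosomal proteins (0.0820) in Depdc5 KO and fatty acid synthesis (0.0834) in Nprl3 KO. Without lines 282 and 263 fatty acid synthesis (0.122, 0.0591 and 0.0593 in Depdc5 KO, Nprl3 KO and the mean of both) and ATF4 targets (0.0931 in Depdc5 KO, 0.154 in the mean of both) lost their calls, and without chromosomes 11 and 19 fatty acid synthesis (0.549) and ribosome biogenesis (0.0649) did in the mean of both, as did nucleotide synthesis (0.137) without the 5 chromosomes. Leaving out 1 line gave 7 to 13 lists in Depdc5 KO (7 without 384), 6 to 12 in Nprl3 KO, and 7 to 14 in the mean of both (7 without 2 or 384). Single lines ended these calls, with the highest adjusted p: in Depdc5 KO fatty acid synthesis (0.140; without control 2, 82, 282, 383 or 384 or knockout 388, 392, 394 or 396), ATF4 targets (0.0952; 2, 282, 383, 384, 386, 388 or 389), p53 targets (0.0952; 82, 282, 383, 384, 389, 392, 394 or 396), ribosomal proteins (0.0644; 2, 383, 384, 388, 389 or 394) and oxidative phosphorylation (0.110; 2, 282, 383, 384, 388, 389, 394 or 396). In Nprl3 KO they ended fatty acid synthesis (0.118; 2, 82, 282, 383, 384, 267 or 270), p53 targets (0.113; 2, 82, 132, 282, 383, 384, 268 or 270) and ribosome biogenesis (0.0683; 2, 82, 384 or 270).

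Some changes that were not called reversed: Trp53 in Nprl3 KO was -0.032 with limma-voom and Cdkn1a between the knockouts was -0.076 with the replicate block, and the cause was not tested. Leaving out 1 line gave -0.074 to 0.27 for Trp53 in Nprl3 KO, -0.23 to 0.11 for Nprl3 in the mean of both, and, between the knockouts, -0.17 to 0.039 for Depdc5, -0.052 to 0.12 for Nprl2, -0.42 to 0.42 for Cdkn1a and -0.075 to 0.17 for Mdm2. Alternatives planned for the 9 comparisons not made were not run. Depth limits genes with few counts, such as Cdkn2a, and simulated 2-fold changes were missed more often than 4-fold ones.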

Other observations

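Tests given here were not planned; the values were looked at after the data were seen. Apart from Lifr, Isl1, Elfn1, Ccnd2 and Dlk1, the genes close to 0 in control lines and called higher in both knockouts include Cd36, a scavenger receptor for lipids, with 0 counts over the control lines, 395 over the Depdc5 KO and 301 over the Nprl3 KO lines. Lgals3, which encodes galectin 3, had 0, 230 and 131 counts, and the chemokine gene Ccl9 had 1, 202 and 231. Fry was 151 times higher in Depdc5 KO (95% interval 26.6 to 5986.2) and 130.5 times in Nprl3 KO (23.02 to 5191.9), and Tusc1 181 times (32.1 to 7199.2) and 233 times (41.3 to 9221.8). F11r, a junction protein, was 30.4 times (10.1 to 150.0) and 42.8 times (14.3 to 210.4) higher.

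Nprl3 KO line 263 stood apart in several ways. It held 365 counts of the Y-linked gene Ddx3y, against 0 or 1 in the other lines, and 733 counts of Igll1 and 659 of Vpreb1, which encode the surrogate light chain of pre-B cells. It had more than 3 counts in 20 of the 24 genes close to 0 in control lines. The called rise of Vpreb1 in Nprl3 KO (log2 change 4.29) was lost without this line (adjusted p = 0.504). In the principal components of 500 genes (leading component 42.3% of variance) control lines lay between -50.0 and -21.7 and knockout lines between -6.34, line 263, and 25.7. Correlations of line pairs over genes had a median of 0.927 among control lines, 0.968 among Depdc5 KO, 0.954 among Nprl3 KO and 0.962 between both knockouts, and 0.911 and 0.915 between control and each knockout. Some pairs were closer. Control lines 82 and 132 had r = 0.979, and Nprl3 KO line 268 and Depdc5 KO line 396 had 0.984. Genes with 0 counts in 1 line and at least 5 CPM in the other numbered 4 and 0 for these pairs. Their medians were 58 among control lines and 20.5 between both knockouts. Whether close lines share an origin was not tested. No pair of libraries differed by as little as sampling noise (smallest chi-square per degree of freedom 3.25). This speaks only to repeats of the same sample, not to how related the lines are.

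Other chromosomes were shifted in some lines. Control line 2 stood at 0.39 on chromosome 10, 0.49 on 15, 0.46 on 16 and 0.41 on 18, and Control line 383 at 0.30 on 15 and 16 and 0.24 on 18. Control line 282 stood at 0.37 on chromosome 1, Nprl3 KO line 263 at 0.55 on 12 and 0.53 on 18, and Depdc5 KO line 388 at 0.27 on 9. In simulated data chromosome 19 was shifted by 0.58 in all 6 control lines. The mean of the control lines then differed from that of the knockout lines by 0.56, and by at most 0.02 on another chromosome. These are differences of group means, so they do not measure the noise of a single line's median and cannot test the shifts of single lines.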
